A study of Escherichia coli str. K-12 substr. MG1655 with 30 samples.

How the data were processed

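RNA was taken from fermentor cultures of E. coli K-12 MG1655 and its mutants grown in MOPS medium with glucose and amino acids, purified on columns, treated with DNase, copied into cDNA with random hexamers, labelled with biotin and hybridized to Affymetrix arrays, per the labels. Of the 30 arrays, 16 form the strain experiment (8 groups of 2) and 14 the time course (2 replete controls and 12 starved time points), on 2 array designs.

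The values are log2 signals that the authors made with RMA, which corrects the background, normalizes the arrays to one distribution and summarizes the probes of each probe set. The version of RMA and which arrays were normalized together are not given in the sources used here. The deposited tables also hold log2 differences from the replete controls, which were checked against the arrays with a tolerance of 0.002. They matched in all 5617 probe sets of the time course and in all gene probe sets of the strain experiment. They differed in 466 intergenic probe sets for crp, dksA and rpoS and in 465 of these for lrp. For 462 of the 466, the value implied by the authors' differences is the array value of the next probe set. In the 466 the array values correlated with starved wild type at r = 0.096 and the implied values at r = 0.944. The array values thus appear to be the misplaced ones. The deposited differences were not used for tests. The files held 14 per-sample columns that match no label and were not used. The genotype field gives relA and relA spoT the other way round from the titles. The titles were used, since the authors' relA differences equal those of the arrays titled relA in all 5610 probe sets and those of the arrays titled relA spoT in 25.

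Tests used gene probe sets that the authors tie to a K-12 locus tag, 4222 in the strain experiment and 4320 in the time course, each gene with 1 probe set. Left out were intergenic probe sets (1382 and 1297) and 6 probe sets with no K-12 tag. The plan had left out probe sets of other strains, but 167 probe sets named for another strain are tied to a K-12 tag by the authors and were kept, and were left out in an alternative. Of the tags, 4141 and 4164 are in the RefSeq gene table. Genome positions were not used here. No filter on signal was applied, and the values were tested as deposited.

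The comparisons, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The strain arrays were fitted in limma (version 3.58.1, R 4.3.3) with a mean per group, so that the 8 groups share one estimate of the spread (8 residual degrees of freedom, 5.64 prior). Wild type with and without isoleucine, each starved strain against replete wild type and each starved strain against starved wild type were compared with moderated two-sided tests, and Benjamini-Hochberg adjusted p under 0.05 over all genes was taken as a call. Errors of differences are standard errors of the contrast. The time-course arrays were fitted with 4 groups: control, and early, middle and late, each of 4 consecutive time points (10 residual degrees of freedom, 4.47 prior). A trend over the starved time points was tested with limma's F test of a natural spline with 3 degrees of freedom. Like the fit with 4 groups, it treats neighbouring samples of a culture as independent. The labels do not give the time of growth arrest in the time course.

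The 23 gene lists were written from textbook knowledge: branched-chain amino acid synthesis, other amino acid synthesis, ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, RpoS-dependent stress genes, Lrp-activated genes, Lrp-repressed genes, CRP-dependent carbon catabolism, TCA and glyoxylate cycle, flagella and chemotaxis, heat shock genes, sigma-E genes, nucleotide synthesis, fatty acid and phospholipid synthesis, ATP synthase and NADH dehydrogenase, nitrogen-limitation genes, universal stress proteins, toxin-antitoxin modules, SOS response, DNA replication and cell division, iron acquisition, and RNA polymerase and growth-phase regulators. Some genes are in several lists. Each list was tested with camera in limma against all other genes, with the correlation between genes preset at 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. Counts of members past the threshold are given over all genes tested and, where it differs, adjusted over the list alone. Medians of log2 differences are over all members of a list.

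Named genes are the 6 mutated genes in each comparison and, among genes past the threshold whose arrays in one group all lie above those in the other, the 8 largest rises and 8 largest falls in starved against replete wild type and in late against control, and the 5 and 5 largest in each starved strain against starved wild type. In each list spoken of, up to 3 called members with the largest change are named. Other names, such as ilvB and ilvN late in the time course, the further CRP-dependent genes in crp, leuB in lrp, and the genes named from comparisons of lists between strains, were chosen after their values were seen.

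The midpoint of the rise of a gene was the first time, by linear interpolation, at which its value crossed midway between the means of the first 2 and last 2 time points, for genes rising by at least 1 log2. A gene already past its midpoint at the first sample was given the time of that sample. Genes low in both strains were left out. Medians were compared with a two-sided permutation test over genes (100000 resamples). The number of list members lower in dksA than in rpoS was compared with the rate over all genes by a one-sided Fisher's exact test. Genes that responded in the time course and were changed in the opposite direction in a strain were counted, with the number chance would give beside each count. The selection and the strain difference share no array.

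Alternatives were quantile normalization, centring of each array on its median, leaving out dim probe sets, a minimum change of 1 log2, a trend in the variance prior, all probe sets, only the groups compared in the fit, array weights, the replicate number as a block, leaving out each array in turn, other time windows and splines, an estimated correlation between list members, and the comparison of each strain of the later submission block with the other 3. Added after seeing the data were fits without the arrays of narrow spread, without the probe sets named for another strain, and with the within-block comparison for gene lists and quantile normalization for the counts by strain.

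Signal over the intergenic background sets what arrays can detect, and the number of arrays limits the precision. The procedure was tested on simulated data with genes of known change added to independent normal noise. Its spread was that of the fit for each gene, equal on all arrays. Narrow or discordant arrays, correlation between genes and serial sampling were not simulated, so the numbers below do not cover them. In a comparison of 2 strains, 18 of 100 genes with a change of 1 log2 and 89 of 100 with a change of 2 log2 were called, beside 7 unchanged genes. Late against control gave 77 and 99 of 100, beside 3 unchanged genes, and the spline 26 and 93. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.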

Results

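Transcript levels of Escherichia coli K-12 MG1655 and 6 strains derived from it were measured on 30 Affymetrix arrays, before and after isoleucine ran out. In the strain experiment, 16 arrays formed 8 groups of 2. One group was wild type with 400 uM isoleucine, sampled at an optical density of 0.4 (replete wild type). The other 7 were wild type, relA, relA spoT, dksA, rpoS, lrp and crp strains grown on 60 uM isoleucine and sampled 40 min after growth stopped (starved strains). In the time course, 14 arrays held 2 replete wild-type controls and 12 single samples of a starved wild-type culture from 340 to 493 min after inoculation. RelA and SpoT make the starvation signal ppGpp, DksA acts with it on RNA polymerase, RpoS is the stress sigma factor, and Lrp and Crp are global regulators of amino acid and carbon metabolism. The labels do not state that replicates came from separate cultures, so the p-values measure the spread between these samples.

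Gene signals lay above the intergenic background: the median log2 signal of genes was 7.37 to 7.64 on the strain arrays and that of intergenic probe sets 5.26 to 6.01. Replicate arrays correlated across genes, which are not independent replicates, at Pearson r 0.959 to 0.987 in 7 of the 8 groups. The exception was the relA group (r = 0.841), whose replicate 2 had a narrower spread of gene values (SD 1.64 log2) than its replicate 1 (SD 2.06). The crp arrays (SD 1.67 and 1.55) and dksA arrays (SD 1.61 and 1.53) were narrower too, against SD 1.84 and 2.02 in starved wild type. In the time course the 2 controls correlated at r = 0.998. The number of arrays limits the precision of every value.

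Each mutated gene had a low transcript signal in its own strain. Against starved wild type, relA (b2784) was lower by -3.44 ± 0.46 log2 (SE, n = 2 arrays per group, as throughout this experiment) in the relA strain, adjusted p = 0.000107, and by -3.74 ± 0.46 in the relA spoT strain, adjusted p = 3.64e-05. The spoT transcript (b3650) differed by -2.88 ± 0.28 in relA spoT, adjusted p = 5.07e-06, and by 0.67 ± 0.28 in relA, adjusted p = 0.0995. Differences of -3.07 ± 0.58 for dksA (b0145), -4.94 ± 0.58 for rpoS (b2741), -3.83 ± 0.49 for lrp (b0889) and -6.47 ± 0.45 for crp (b3357) were found in the respective strains, with adjusted p = 0.00224, 0.00019, 0.00195 and 2.46e-06. The genotype field of the labels gives the relA and relA spoT arrays the other way round from the sample titles. The titles were kept, and the low spoT signal lies in the arrays titled relA spoT. The crp, dksA, lrp and rpoS arrays belong to a later submission block than the wild-type, relA and relA spoT arrays, so block and strain cannot be told apart in their comparison with wild type. Against the mean of the other 3 strains of that block, the differences were -5.95 ± 0.37 for crp, -2.41 ± 0.47 for dksA, -3.00 ± 0.40 for lrp and -4.19 ± 0.48 for rpoS.

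**Figure D1:**
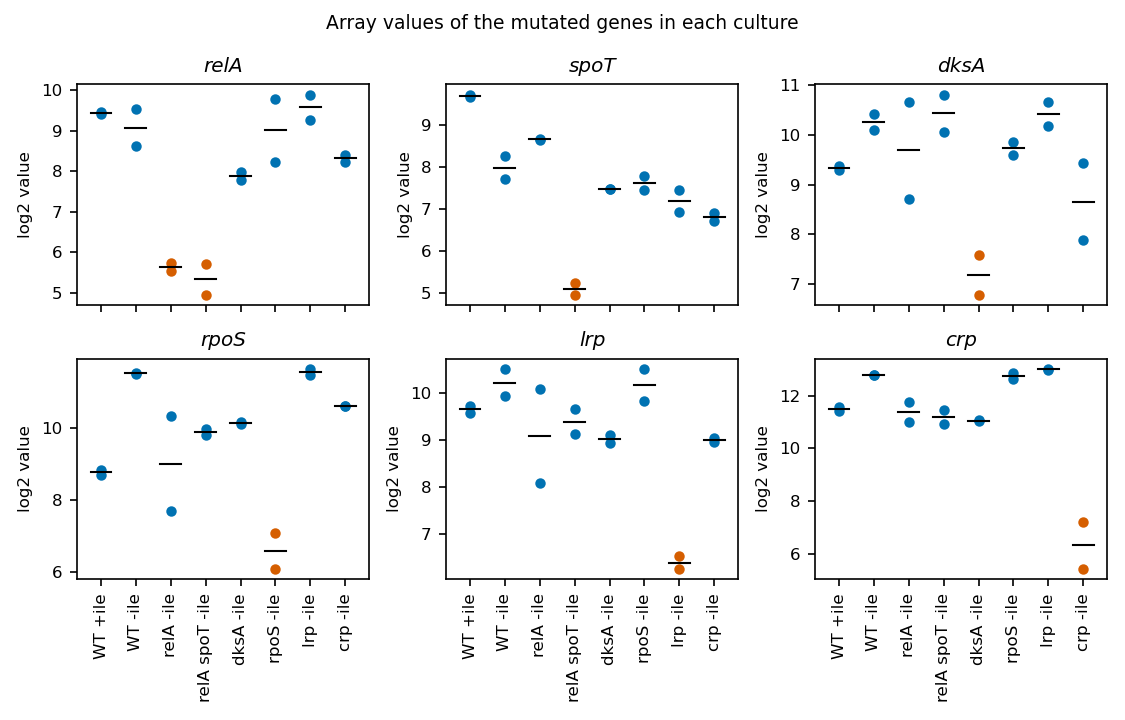
Transcript level (log2 RMA value) of relA, spoT, dksA, rpoS, lrp and crp in the 8 groups of the strain experiment, with a point per array, a black line at the mean of the 2 arrays and orange for strains that carry the mutation. The lowest mean of each gene lies in a strain that lacks it, as for crp at 6.32 against 12.79 in starved wild type.

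How wild type responded to the loss of isoleucine was asked by comparing starved with replete wild type. Genes for making branched-chain amino acids rose, 11 of 18 (12 adjusted over the list alone), with a median difference of 2.13 log2 over the list. Among them were leuA (4.73 ± 0.44), ilvM (4.63 ± 0.26) and ilvG (4.51 ± 0.33). RpoS-dependent stress genes rose in 47 of 56 cases (50 adjusted over the list alone, median 2.83), led by elaB (4.71 ± 0.45), yiaG (4.68 ± 0.28) and yeaG (4.63 ± 0.24). Flagella and chemotaxis genes fell, 51 of 52 (52 adjusted over the list alone, median -4.00), and so did 22 of 26 genes of nucleotide synthesis (25 adjusted over the list alone, median -3.00). Ribosomal protein genes fell in 39 of 54 cases (51 adjusted over the list alone, median -1.39), such as rplI (-3.19 ± 0.50), rpsU (-2.93 ± 0.71) and rpsO (-2.92 ± 0.54). The largest rises were those of cysD (6.74 ± 0.44), cysN (6.39 ± 0.43), cysJ (5.86 ± 0.35), cysP (5.82 ± 0.41), cysH (5.64 ± 0.30) and cysI (5.38 ± 0.40), whose products take up and reduce sulfate. Next came rmf (5.38 ± 0.55), a ribosome hibernation factor, and yohC (5.08 ± 0.49). The deepest falls were those of the flagellar genes flgB (-7.14 ± 0.27), flgE (-6.90 ± 0.38), flgC (-6.06 ± 0.43), flgD (-5.84 ± 0.36) and flgF (-5.81 ± 0.28). The pyrimidine genes pyrB (-6.55 ± 0.52), pyrI (-6.31 ± 0.38) and carA (-6.29 ± 0.40) fell by similar amounts. Of the mutated genes, rpoS rose by 2.75 ± 0.59 (adjusted p = 0.0035) and spoT fell by 1.71 ± 0.28 (adjusted p = 0.000457). Values for relA (-0.36), dksA (0.92), lrp (0.57) and crp (1.29 ± 0.45) did not pass, with adjusted p = 0.724, 0.341, 0.536 and 0.0557.

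Smaller groups moved as well in starved wild type. Universal stress protein genes rose in 5 of 7 cases (6 adjusted over the list alone, median 2.89), including uspE (3.47 ± 0.44). Of 18 toxin-antitoxin genes 8 rose (9 adjusted over the list alone, median 0.93), including relE (2.26), mqsR (2.18) and mqsA (2.04). Among translation factors 5 of 11 fell (7 adjusted over the list alone, median -1.07), with prfC at -2.10 ± 0.45 and infA at -2.00 ± 0.34. Of 16 Lrp-repressed genes 6 fell and 1 rose (10 and 2 adjusted over the list alone, median -1.09), with ompC at -1.93 and livK at -1.77. The list test (camera) passed for these 4 groups and for the 5 above. It gave adjusted p = 1.01e-08 for branched-chain amino acid synthesis, 5.75e-32 for RpoS-dependent genes, 2.53e-57 for flagella, and 6.18e-19 each for ribosomal proteins and nucleotide synthesis. The smaller groups gave adjusted p = 3.42e-05 for universal stress proteins, 0.000115 for toxin-antitoxin genes, 0.00267 for translation factors and 0.00642 for Lrp-repressed genes. With an estimated correlation only the RpoS-dependent (adjusted p = 0.00176) and flagella lists (0.00451) still passed. Nucleotide synthesis then gave adjusted p = 0.104, universal stress proteins 0.114, branched-chain amino acid synthesis 0.138, ribosomal proteins, Lrp-repressed and toxin-antitoxin genes 0.199 each, and translation factors 0.365.

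The other 14 lists did not pass the list test in starved wild type, though single members did. Other amino acid synthesis had 13 genes up and 6 down of 67 (14 and 6 adjusted over the list alone, median 0.19, adjusted p = 0.0672), with cysD, cysN and cysJ up. Lrp-activated genes had 5 up and 2 down of 18 (the same adjusted over the list alone, median 0.42, adjusted p = 0.0672), with leuA, leuC (3.51) and leuB (3.39) up. CRP-dependent carbon catabolism had 5 up and 11 down of 84 (the same adjusted over the list alone, median -0.12, adjusted p = 0.107), with tsx (-3.21 ± 0.38) and rbsD (-3.19 ± 0.29) down. The TCA cycle list had 2 up and 4 down of 20 (median -0.27, adjusted p = 0.514), with acnA at 2.17 and sucB at -1.63. Fatty acid synthesis had 2 up and 5 down of 21 (median -0.41, adjusted p = 0.0971), with accB at -3.31 ± 0.60. Aminoacyl-tRNA synthetases had 2 down of 23 (1 adjusted over the list alone, median -0.38, adjusted p = 0.124), ATP synthase and NADH dehydrogenase 1 down of 21 (0 adjusted over the list alone, median -0.54, adjusted p = 0.0557). DNA replication had 3 down of 25 (median -0.31, adjusted p = 0.136). Heat shock genes had groS down and rpoH up of 17 (neither adjusted over the list alone, median -0.10, adjusted p = 0.514). No sigma-E gene of 17 passed limma's adjusted threshold (median -0.25, adjusted p = 0.443), where 1317 of all genes had an unadjusted p under 0.05. Of 19 nitrogen-limitation genes 3 rose and 3 fell, glnA by -4.59 ± 0.35 (list median 0.12 although the test points down, adjusted p = 0.738). SOS genes had 3 up of 19 (median 0.00, adjusted p = 0.704), iron acquisition 3 up and 2 down of 35 (median -0.21, adjusted p = 0.43). RNA polymerase and growth-phase regulators had 3 up and 3 down of 21 (5 and 3 adjusted over the list alone, median 0.38, adjusted p = 0.704), with fis, a regulator of fast growth, at -3.57 ± 0.40.

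In all, 898 of 4222 genes differed between starved and replete wild type, 470 higher and 428 lower. The count was 589 without starved replicate 1, 547 without replete replicate 1 and 573 without replete replicate 2.

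The submitters compared each starved mutant with replete wild type. No replete mutant was measured, so these differences hold effects of the strain as well as of starvation. Flagella genes were lower than in replete wild type in every starved strain, in 49 of 52 genes in relA (median -4.32), 50 in relA spoT (-4.68), 49 in dksA (-3.60), 51 in rpoS (-3.92), 50 in lrp (-3.82) and 49 in crp (-3.74). Adjusted over the list alone the counts were 49 to 52. The list test gave adjusted p between 2.74e-65 and 9.57e-42, and adjusted p between 0.00573 and 0.0203 with an estimated correlation. RpoS-dependent genes were higher in 42 of 56 cases in lrp (44, with 1 lower, adjusted over the list alone, median 2.67, adjusted p = 1.16e-22) and 49 in crp, with 1 lower (49 and 2 adjusted over the list alone, median 2.33, adjusted p = 1.68e-19), also with an estimated correlation (adjusted p = 0.00604 and 0.0105). In relA 1 of them was higher and 8 lower (median -0.06, adjusted p = 0.358) and in relA spoT 4 and 7 (4 and 5 adjusted over the list alone, median -0.15, adjusted p = 0.216). In dksA 11 were higher and 3 lower (median 0.59, adjusted p = 0.00454, and 0.478 with an estimated correlation), and in rpoS 13 and 2 (14 and 2 adjusted over the list alone, median 0.41, adjusted p = 0.00149, and 0.19 with an estimated correlation). The spoT transcript was lower than in replete wild type in all 6 starved mutants. The difference was -1.04 ± 0.28 in relA (adjusted p = 0.0198), -2.22 ± 0.28 in dksA, -2.08 ± 0.28 in rpoS, -2.51 ± 0.28 in lrp, -2.89 ± 0.28 in crp and -4.59 ± 0.28 in relA spoT, which lacks the gene.

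Ribosomal protein genes were lower than in replete wild type in 41 of 54 cases in rpoS (53 adjusted over the list alone, median -1.60, adjusted p = 2.93e-23), 46 in lrp (52 adjusted over the list alone, median -1.91, adjusted p = 3.74e-20) and 53 in crp (median -2.77, adjusted p = 1.41e-28). In dksA 13 were lower (11 adjusted over the list alone, median -0.56, adjusted p = 6.04e-05). With an estimated correlation these gave adjusted p = 0.155, 0.241, 0.178 and 0.501. No ribosomal gene passed limma's test in relA (list median 0.04, adjusted p = 0.924), where 1272 of all genes had an unadjusted p under 0.05. In relA spoT 1 was higher (none adjusted over the list alone, list median 0.33, adjusted p = 0.037, and 0.737 with an estimated correlation). Nucleotide synthesis genes were lower in 22 to 25 of 26 cases in dksA (median -2.98), rpoS (-3.13), lrp (-3.99) and crp (-3.37), or 22 to 26 adjusted over the list alone. In relA 10 were lower (14 adjusted over the list alone, median -1.53) and in relA spoT 7 (median -0.51). The list test gave adjusted p between 1.2e-21 and 0.00176 in the 6 strains, and adjusted p between 0.082 and 0.583 with an estimated correlation. Branched-chain synthesis genes were higher in 12 of 18 cases in rpoS (15 adjusted over the list alone, median 2.36, adjusted p = 3.81e-10, and 0.144 with an estimated correlation), and 8 in lrp (8, with 1 lower, adjusted over the list alone, median 0.59, adjusted p = 0.0201, and 0.531 with an estimated correlation). In crp 7 were higher (median 0.75, adjusted p = 0.0168, and 0.458 with an estimated correlation). The list did not pass in relA (4 higher, 3 lower, or 5 and 6 adjusted over the list alone), relA spoT (4 and 7) or dksA (3 and 3, or 3 and 5 adjusted over the list alone). It gave adjusted p = 0.924, 0.253 and 0.714. Lrp-activated genes were lower in relA (9 of 18, or 13 adjusted over the list alone, median -1.57, adjusted p = 1.16e-06, and 0.302 with an estimated correlation) and relA spoT (13, median -1.80, adjusted p = 1.13e-06, and 0.268 with an estimated correlation). In lrp 10 were lower and 3 higher (13 and 3 adjusted over the list alone, median -1.70, adjusted p = 0.00341, and 0.531 with an estimated correlation). After quantile normalization the dksA calls for ribosomal proteins (median -0.03, adjusted p = 0.477) and RpoS-dependent genes (median 0.49, adjusted p = 0.0508) and the relA spoT call for ribosomal proteins (median 0.24, adjusted p = 0.125) were lost.

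**Figure D2:**
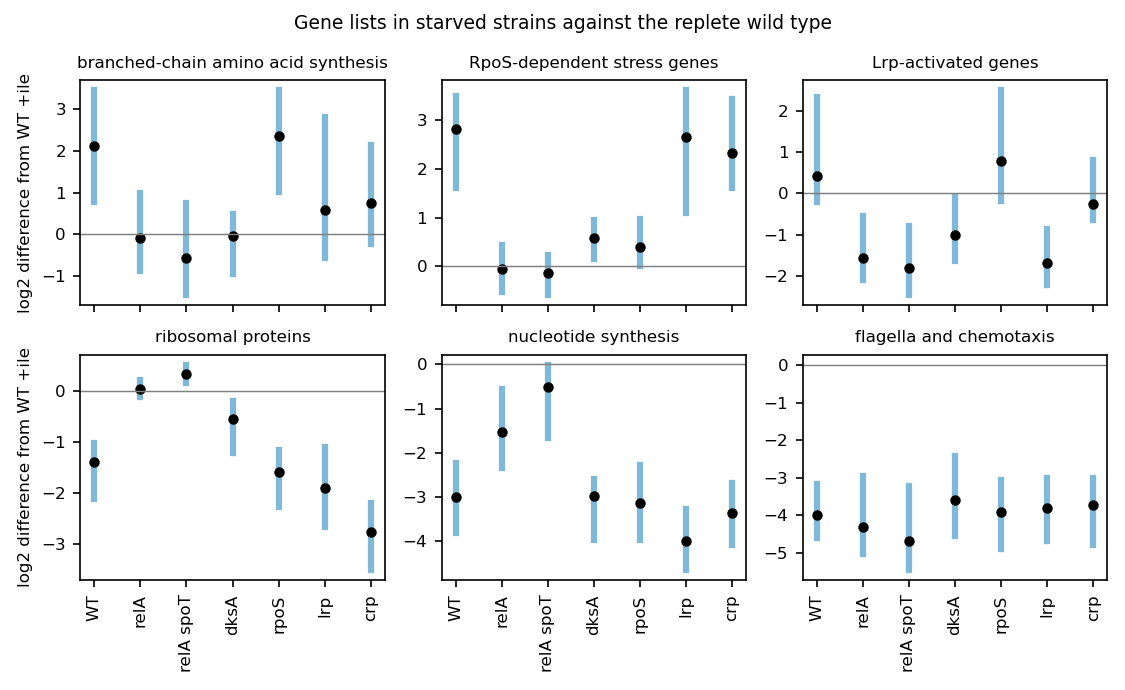
Median log2 difference from replete wild type (points) with the quartiles over members (bars) for 6 gene lists in the 7 starved strains. RpoS-dependent genes have medians of 2.83, 2.67 and 2.33 in wild type, lrp and crp and between -0.15 and 0.59 in the other 4 strains, while flagella genes lie between -4.68 and -3.60 in all 7.

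Against replete wild type 738 genes differed in relA (354 higher, 384 lower), 980 in relA spoT (556 and 424), 1216 in dksA (583 and 633), 777 in rpoS (359 and 418), 1103 in lrp (501 and 602) and 1449 in crp (716 and 733). Centring each array moved the dksA split to 387 higher and 732 lower, and scaling moved the median of all genes by up to 0.147 log2 in dksA and 0.134 in crp. With only the compared groups in the fit 202 passed in relA and 2237 in dksA. Leaving out replete wild-type replicate 1 gave 375 genes in relA, 564 in relA spoT, 539 in dksA, 411 in rpoS, 698 in lrp and 844 in crp. Leaving out replete replicate 2 gave 377, 556, 528, 447 and 867 in relA, relA spoT, dksA, rpoS and crp. Of the mutants' own arrays, relA replicate 1 (1650), relA spoT replicate 2 (593), dksA replicates 1 (759) and 2 (523), rpoS replicate 1 (455) and crp replicate 2 (834) moved their count by as much.

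Genes whose level under starvation differs without RelA were sought by comparing starved relA with starved wild type. The relA strain keeps spoT, and ppGpp was not measured in these data. RpoS-dependent stress genes were lower in relA, 49 of 56 (50 lower and 1 higher adjusted over the list alone, median -2.74), such as yiaG (-5.60 ± 0.28), msyB (-5.16) and dps (-4.99). The rpoS transcript itself was lower by -2.51 (adjusted p = 0.006). Branched-chain synthesis genes were lower in 15 of 18 cases (17 adjusted over the list alone, median -1.54), led by leuC (-5.38 ± 0.37), leuA (-4.72) and leuD (-4.61), with ilvY (0.99 ± 0.27), a regulator of ilvC, higher. Ribosomal protein genes were higher in 39 of 54 cases (50 adjusted over the list alone, median 1.61), for example rpsR (3.39), rplI (3.23) and rpmH (3.06). Nucleotide synthesis genes were higher in 16 of 26 cases (median 1.53), among them ndk (3.33), purK (3.12) and carA (2.97). TCA cycle genes were lower in 13 of 20 cases (14 adjusted over the list alone, median -1.90), including aceB (-3.33) and acnA (-3.23), and Lrp-activated genes in 14 of 18 (15 adjusted over the list alone, median -2.50). Apart from these, the largest differences were those of yhbE (4.94 ± 0.34), higB (4.79 ± 0.38), cspF (4.49 ± 0.31), tpr (4.46 ± 0.54) and ygiS (3.93 ± 0.37) upward and of rmf (-6.25 ± 0.55), sra (-6.24 ± 0.38) and fbaB (-5.26 ± 0.29) downward. The crp transcript was lower by -1.41 (adjusted p = 0.0322).

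The list tests of relA against starved wild type gave adjusted p = 1.88e-33 for RpoS-dependent genes (0.00144 with an estimated correlation), 1.54e-08 for branched-chain synthesis, 1.36e-16 for ribosomal proteins, 4.4e-07 for nucleotide synthesis, 2.58e-07 for the TCA cycle and 7.35e-08 for Lrp-activated genes. With an estimated correlation the last 5 gave adjusted p = 0.259, 0.296, 0.304, 0.296 and 0.296. In all, 1081 genes differed (470 higher, 611 lower). Without relA replicate 1 the count was 1781 and without starved wild-type replicate 2 it was 669. With only the compared groups in the fit it was 235 and with array weights 410.

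The relA spoT strain, which lacks both enzymes that make ppGpp, was compared with starved wild type in the same way. RpoS-dependent genes were lower in 51 of 56 cases (53 adjusted over the list alone, median -2.85), among them yiaG (-5.63), yeaG (-5.18) and yccJ (-5.01). Branched-chain synthesis genes were lower in 17 of 18 cases (median -2.07), with leuC at -5.42, leuA at -4.89 and leuD at -4.76. Ribosomal protein genes were higher in 48 of 54 cases (50 adjusted over the list alone, median 1.87), led by rplI (4.27 ± 0.51), rpmC (4.12 ± 0.74) and rpsI (3.45). Nucleotide synthesis genes were higher in 19 of 26 cases (21 adjusted over the list alone, median 2.07), led by purK (3.69), purE (3.63) and purM (3.62). Translation factor genes were higher in 6 of 11 cases (median 1.44, adjusted p = 0.000757, and 0.267 with an estimated correlation) and fis by 3.49. The largest rises were those of bdcA (6.25 ± 0.46), tpr (5.40), yhbE (5.25), cspF (4.42) and higA (4.37), and rmf (-5.96), fbaB (-5.65) and sra (-5.34) were among the deepest falls. The rpoS transcript was lower by -1.63 (adjusted p = 0.0453) and crp by -1.58 (adjusted p = 0.014). In the list test RpoS-dependent genes gave adjusted p = 5.68e-28 (0.00275 with an estimated correlation), branched-chain synthesis 2.07e-09, ribosomal proteins 4.01e-19 and nucleotide synthesis 6.75e-10. With an estimated correlation these last 3 gave adjusted p = 0.189, 0.215 and 0.215. In all, 1409 genes differed (702 higher, 707 lower).

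DksA was compared in the same way. RpoS-dependent genes were lower in starved dksA than in starved wild type, 44 of 56 (49 adjusted over the list alone, median -2.23), with yiaG (-5.02 ± 0.28), yjbJ (-4.27) and elaB (-4.16) among them, although the rpoS transcript (-1.38, adjusted p = 0.0976) did not pass. Branched-chain synthesis genes were lower in 16 of 18 cases (median -2.15), including leuC (-4.53 ± 0.37), leuA (-4.13) and ilvD (-3.41). Ribosomal protein genes were higher in 19 of 54 cases (25 adjusted over the list alone, median 0.89), such as rplA (2.25) and rpsQ (2.18), whereas nucleotide synthesis had 3 genes higher and 1 lower of 26 (adjusted p = 0.782). Other large differences were those of the cold shock gene cspA (3.12 ± 0.60), maoP (3.03 ± 0.42), fruB (2.97 ± 0.55), mokB (2.84 ± 0.49) and yhbE (2.82 ± 0.34). Lower were yahO (-5.27 ± 0.62), uspA (-5.06 ± 0.55), the iron storage gene bfr (-4.63 ± 0.26), the glyoxylate cycle gene aceA (-4.24 ± 0.36) and serA (-3.80 ± 0.58). Flagella genes were higher in 12 of 52 cases and lower in fliC (-2.47 ± 0.69), with adjusted p = 0.00156 for the list (0.5 with an estimated correlation, 0.206 after quantile normalization).

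Within the later block, ribosomal protein genes were higher in dksA in 37 of 54 cases (median 1.47, adjusted p = 8.34e-19, and 0.258 with an estimated correlation). The other 3 strains include crp, in which these genes were low (median -1.086 against starved wild type), which raises this median. Branched-chain genes were lower in 12 cases (median -1.37, adjusted p = 2.54e-09, and 0.258 with an estimated correlation). RpoS-dependent genes were lower in 33 (median -1.23, adjusted p = 2.75e-16, and 0.0186 with an estimated correlation). There cspA differed by 2.51, maoP by 3.19, yhbE by 2.54, yahO by -4.31, uspA by -3.65, yiaG by -3.72, bfr by -3.21, leuC by -3.30 and aceA by -3.08, and fliC (-1.08) did not pass. With starved wild type as the reference the list tests gave adjusted p = 9.07e-26 for RpoS-dependent genes, 7.23e-11 for branched-chain synthesis and 6.77e-07 for ribosomal proteins, and adjusted p = 0.00368, 0.188 and 0.5 with an estimated correlation. The 1107 genes that differed (490 higher, 617 lower, or 551 and 484 after quantile normalization) became 631 without dksA replicate 1, 467 without dksA replicate 2, 411 without starved wild-type replicate 2 and 1671 without either relA array in turn.

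The rpoS strain was compared with starved wild type to find the genes that need this sigma factor. RpoS-dependent genes were lower, 33 of 56 (47 adjusted over the list alone, median -2.01), with the largest differences in yjbJ (-4.63 ± 0.39), yiaG (-4.53 ± 0.28), osmY (-4.52 ± 0.55) and yeaG (-4.05 ± 0.24). The universal stress gene uspB was lower by -2.27 ± 0.36. Within the later block the same genes differed by -3.03 (yjbJ), -3.06 (yiaG), -3.04 (osmY), -2.84 (yeaG) and -1.15 (uspB), and 32 list members were lower and 2 higher (median -1.21, adjusted p = 2.6e-21, and 0.00713 with an estimated correlation). Against starved wild type the list gave adjusted p = 1.16e-99 (2.08e-05 with an estimated correlation), and it alone of the 23 lists passed. In limma 83 genes were lower and 0 higher, with 226 genes at an unadjusted p under 0.05 in either direction. Without rpoS replicate 2 the count was 54 and without starved wild-type replicate 2 it was 50. Within the block it was 269.

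In the lrp strain 21 genes differed from starved wild type, 4 higher and 17 lower. Of 18 Lrp-activated genes 6 were lower (16 adjusted over the list alone, median -1.96), namely fimA (-5.56 ± 0.65), which encodes the main fimbrial subunit, serA (-3.29 ± 0.58), gltD (-3.02 ± 0.32), leuD (-2.49), leuC (-2.43) and leuB (-2.06). The fimbrial genes fimI (-4.04 ± 0.59) and fimC (-3.29 ± 0.60) were lower as well. Of the Lrp-repressed genes livJ (3.26 ± 0.33), for branched-chain amino acid transport, and lysU (2.05 ± 0.41), a lysyl-tRNA synthetase, were higher. That list did not pass (2 higher and 4 lower adjusted over the list alone, median -0.03 although the test points up, adjusted p = 0.564). Higher as well were flu (1.91 ± 0.30) and ygiW (1.44 ± 0.27). Branched-chain synthesis genes were lower in 4 of 18 cases (9 lower and 1 higher adjusted over the list alone, median -1.06), with thrB at -2.30. The other called members, leuD, leuC and leuB, are those counted above in the Lrp-activated list, so the list results are not separate.

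Within the later block livJ (3.47), lysU (1.92), flu (1.49), fimA (-4.45), fimI (-4.19), fimC (-3.86) and gltD (-2.22) also differed in lrp, and 6 Lrp-activated genes were lower (median -1.14, adjusted p = 4.91e-09, and 0.275 with an estimated correlation). The within-block values of serA (-1.66, adjusted p = 0.0509), leuD (-0.87, adjusted p = 0.148), leuC (-0.50, adjusted p = 0.368) and thrB (-1.12, adjusted p = 0.07) did not pass, nor did the branched-chain list (adjusted p = 0.866). The reference there includes dksA, in which leuC (-3.30 within the block) and serA (-2.34) were low, which lessens these differences. Against starved wild type the list tests gave adjusted p = 2.18e-32 for Lrp-activated genes (0.0428 with an estimated correlation) and 7.87e-10 for branched-chain synthesis (0.238 with an estimated correlation). Of the 23 lists 12 passed with the preset correlation and 1 with an estimated one. The count of 21, with 247 genes at an unadjusted p under 0.05, became 7 without lrp replicate 2, 4 without starved wild-type replicate 2 and 42 without either relA array in turn, and was 277 within the block.

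In the starved crp strain the deepest falls from starved wild type after crp itself were those of glpD (-4.91 ± 0.27), a gene of glycerol use that Crp activates, the stress genes uspA (-3.78 ± 0.55) and uspG (-3.78 ± 0.56) and the transporter gene tcyP (-3.35 ± 0.39). Higher were crl (3.59 ± 0.34), whose product aids RpoS, ycaP (2.49 ± 0.48), intR (2.27 ± 0.42), ygaC (2.0 ± 0.39) and ypjC (1.97 ± 0.45). Ribosomal protein genes were lower in 24 of 54 cases (35 adjusted over the list alone, median -1.09), for example rpmF (-2.99 ± 0.48), rpsS (-2.58) and rpsC (-2.53). TCA cycle genes were lower in 7 of 20 cases (11 adjusted over the list alone, median -1.24), among them sdhC (-2.48) and sdhD (-2.04). Branched-chain synthesis genes were lower in 6 of 18 cases (14 adjusted over the list alone, median -1.08), with ilvE at -2.52. Of 84 CRP-dependent genes 3 were lower, glpD, glpK (-2.61 ± 0.33) and deoC (-1.09 ± 0.32). Another 4 were higher, the sugar genes fucP (1.53 ± 0.36), mglA (1.32 ± 0.30), malP (1.29 ± 0.32) and fucI (1.03 ± 0.25). The list did not pass (median 0.22, adjusted p = 0.252). RpoS-dependent genes were lower in 5 of 56 cases and higher in 1 (9 and 1 adjusted over the list alone, median -0.34, adjusted p = 0.0217, and 0.416 with an estimated correlation), but their median was 0.03 after quantile normalization.

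Within the later block crp had 36 of 54 ribosomal protein genes lower (median -1.34, adjusted p = 5.65e-28, and 0.367 with an estimated correlation). The other 3 strains include dksA, in which these genes were high, which deepens this median. There glpD differed by -4.23, glpK by -1.92, uspA by -1.93, uspG by -2.53, tcyP by -2.44, crl by 3.45 and ycaP by 3.46. The values of ypjC (1.25, adjusted p = 0.0508), sdhC (-1.83, adjusted p = 0.0525), fucP (0.93, adjusted p = 0.0609) and deoC (-0.21, adjusted p = 0.717) did not pass there. RpoS-dependent genes turned to higher there, 31 of 56 (median 1.18, adjusted p = 1.5e-19, and 0.0101 with an estimated correlation), where the other 3 strains include dksA and rpoS, and the branched-chain list did not pass (adjusted p = 0.659). With starved wild type as the reference the adjusted p was 2.24e-15 for ribosomal proteins and 2.28e-06 each for the TCA cycle and branched-chain synthesis, and adjusted p = 0.34 for each with an estimated correlation. In all 425 genes differed (152 higher, 273 lower, or 249 and 217 after quantile normalization). Leaving out crp replicate 2 gave 32, starved wild-type replicate 1 194, starved wild-type replicate 2 77, and either relA array in turn 995.

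The time course followed wild type into starvation, with n = 4 arrays each for its early (340 to 390 min), middle and late (430 to 493 min) parts, 2 controls and single arrays per time point. The 4 arrays of a part are serial samples of a culture that the fit takes as replicates. Its errors, p-values and counts thus hold no spread between starved cultures. They do hold the change within a part. The flagella median, for example, went from -2.216 at 430 min to -4.272 at 493 min. Late in the course RpoS-dependent genes were up against the controls, 53 of 56 (median 2.45), led by ycgB, ecnB (3.92) and yiaG (3.76). Flagella genes fell, 51 of 52 (52 adjusted over the list alone, median -3.03), as did 24 of 26 nucleotide synthesis genes (median -2.56). Ribosomal protein genes fell in 49 of 54 cases (50 adjusted over the list alone, median -1.12), with rpmH at -2.25 and rpsQ at -2.24. Branched-chain synthesis genes rose in 12 of 17 cases (median 0.96), with ilvM (3.89 ± 0.36), ilvD (3.35 ± 0.29) and leuA (3.21 ± 0.27) highest, while ilvB (-1.16 ± 0.20), ilvN (-0.89 ± 0.22) and ilvY (-0.78 ± 0.29) fell. The largest rises were those of cysH (5.55 ± 0.78), cysP (4.95 ± 0.64), cysJ (4.44 ± 0.60), cysD (4.36 ± 0.56), ycgB (4.15 ± 0.48), cysN (4.11 ± 0.63), cysI (4.08 ± 0.65) and cysA (4.04 ± 0.55). The deepest falls were those of flgB (-6.38 ± 0.80), carA (-6.04 ± 0.65), flgD (-5.91 ± 0.70), pyrB (-5.78 ± 0.75), fliL (-5.50 ± 0.55), flgE (-5.45 ± 0.62), pyrI (-5.40 ± 0.56) and flgC (-5.30 ± 0.64). The rpoS transcript rose by 1.91 ± 0.23 (adjusted p = 1.36e-05), crp by 0.89 ± 0.17 and lrp by 0.78 ± 0.26 (adjusted p = 0.0209), and spoT fell by 1.43 ± 0.26 (adjusted p = 0.000402). Values for relA (-0.29, adjusted p = 0.181) and dksA (0.44, adjusted p = 0.107) did not pass.

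The late list tests gave adjusted p = 3.4e-22 for RpoS-dependent genes, 7.37e-24 for flagella, 1.34e-11 for nucleotide synthesis, 1.83e-14 for ribosomal proteins and 0.00036 for branched-chain synthesis. No list passed with an estimated correlation (adjusted p = 0.42 for the first 4 and 0.445 for the fifth). In the time course that correlation includes the shared change of members within a part. Its list tests therefore cannot separate a common trend from correlated noise. In all 2001 of 4320 genes differed (994 higher, 1007 lower), and 1300 without control replicate 2.

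Early in the course branched-chain synthesis genes were already higher than in the controls, 8 of 17 (11 adjusted over the list alone, median 0.78, adjusted p = 1.64e-10, and 0.344 with an estimated correlation), with ilvM (2.68 ± 0.36), ilvD (2.46 ± 0.29) and ilvE (2.11 ± 0.28) leading. Of 18 Lrp-activated genes 4 were higher (5 adjusted over the list alone, median 0.49, adjusted p = 1.87e-05, and 0.514 with an estimated correlation), including leuD (2.07 ± 0.37), leuA (2.02 ± 0.27) and leuB (1.98 ± 0.42). These leu genes are in the branched-chain list as well. No RpoS-dependent gene passed limma's threshold early, although the list did (median 0.41, adjusted p = 3.91e-06, and 0.584 with an estimated correlation), and rpoS itself stood at 0.84 (adjusted p = 0.0887). The early count was 35 genes (18 higher, 17 lower, or 18 and 50 with each array centred, which moved the median of all genes by 0.117), with 717 at an unadjusted p under 0.05. It changed to 179 without the 340 min array, 12 without 380 min, 20 without 390 min, 15 without 400 min, 23 without 430 min, 17 without 445 min or 460 min, and 3 without either control in turn.

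**Figure D3:**
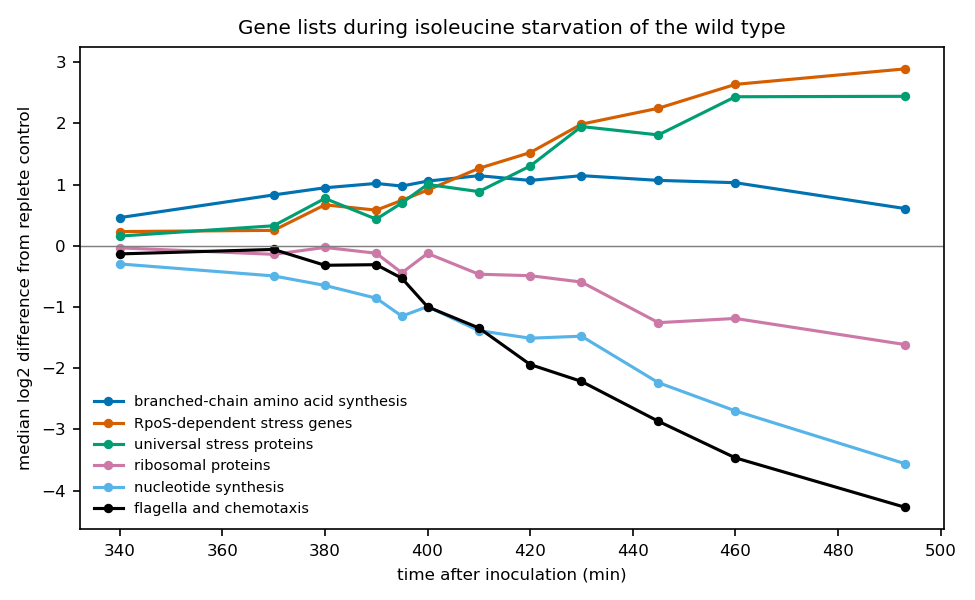
Median log2 difference from the replete controls (y axis) of 6 gene lists against time after inoculation in min (x axis), with a point per single starved array. Branched-chain synthesis is at 0.83 by 370 min, whereas RpoS-dependent genes go from 0.23 at 340 min to 0.91 at 400 min and 2.89 at 493 min, and flagella genes reach -4.27.

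Late against early samples, 1660 genes differed (694 higher, 966 lower, or 898 and 833 after quantile normalization and 1023 and 799 with each array centred, a shift of 0.113 in the median of all genes). RpoS-dependent genes rose between these parts in 52 of 56 cases (median 1.89, adjusted p = 2.21e-27, and 0.31 with an estimated correlation). Flagella genes all fell, 52 of 52 (median -2.88, adjusted p = 1.06e-28, and 0.31 with an estimated correlation). Ribosomal protein genes fell in 50 of 54 cases (52 adjusted over the list alone, median -1.07, adjusted p = 2.37e-17, and 0.348 with an estimated correlation). Single genes included cysH (4.91 ± 0.64), ycgB (3.72 ± 0.39), flgB (-5.99 ± 0.66) and pyrB (-5.13), and rpoS rose by 1.07 ± 0.18. A smooth trend over the 12 starved time points passed in 1753 genes (788 rising, 965 falling, or 1110 and 894 with each array centred).

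Both experiments measured the starved wild type, on different array designs. Across the 4179 genes on both, which are not independent replicates, the late change correlated with the change in the strain experiment at r = 0.916 and the early change at r = 0.582. By time point r went from 0.275 at 340 min through 0.685 at 400 min to 0.912 at 493 min. In both, 432 genes rose (108.1 by chance) and 408 fell (100.5 by chance), cysD, cysH, flgB and pyrB among them, and 0 were called in opposite directions by limma.

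Genes of the response that differed the opposite way between a starved strain and starved wild type were then counted. The response was taken from the time course (967 genes up and 986 down late, of those on both designs) and the strain difference from the other arrays. A gene with a smaller response in the strain is counted as well as a gene with none. Of the rising genes 432 were lower in relA than in starved wild type (44.7%, 141.2 by chance), 478 in relA spoT (49.4%, 163.4 by chance) and 373 in dksA (38.6%, 142.5 by chance). In crp 121 were lower (12.5%, 63.2 by chance), in rpoS 79 (8.2%, 19.2 by chance) and in lrp 12 (3.9 by chance). Falling genes were higher in 303 cases in relA (30.7%, 110.2 by chance), 417 in relA spoT (42.3%, 164.5 by chance) and 152 in dksA (15.4%, 114 by chance). They were higher in 25 cases in crp (34.7 by chance), 2 in lrp and 0 in rpoS, where limma called no gene higher than in starved wild type and 226 genes had an unadjusted p under 0.05. After quantile normalization of the strain arrays the falling genes higher in dksA were 232 (128.1 by chance) and in crp 50 (57.8 by chance). The rising genes lower than in starved wild type were then 309 in dksA (111.8 by chance) and 92 in crp (50.2 by chance). With the response taken from the strain arrays, where the starved wild-type arrays enter both the selection and the difference, the shares of rising genes were 67.9% in relA, 71.9% in relA spoT, 64.5% in dksA, 17.8% in crp and 16.9% in rpoS. The differences between strains in these counts were not tested.

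Finally, the time at which rising genes passed the midpoint of their rise was compared between genes low in rpoS and genes low in lrp. The 6 genes low in lrp, leuD (373.1 min), leuB (374.4), dadX (377.7), leuC (378.9), aceA (384.4) and fimA (397.1), had a median of 378.3 min. Left out of both sets was patA (417.2 min), which was low in both strains. Of the 6 genes leuB (-1.10 ± 0.24) and fimA were lower in lrp within the later block, and leuD, leuC, dadX and aceA did not pass (adjusted p = 0.148, 0.368, 0.549 and 0.897). The reference there includes dksA, in which leuC (-3.30 within the block) and aceA (-3.08) were low. The 77 genes low in rpoS had a median of 413.5 min (quartiles 404.9 and 422.5), later by 35.2 min in a two-sided permutation test over genes, which are not independent replicates (p = 1e-05, the smallest these resamples can give). Without the 340 min array 1 lrp gene was left and the difference was 8.1 min (permutation p = 0.573). Measured from the replete controls in place of the first time points, it was 43.3 min over 7 genes low in lrp (permutation p = 2e-05). These controls had 400 uM isoleucine, and branched-chain genes stood 0.461 above them at 340 min. Of the fixed lists, the members that rose by at least 1 log2 passed their midpoint at a median of 378.6 min in branched-chain synthesis (8 of 17 members), 378.9 in Lrp-activated genes (5 of 18) and 394.3 in toxin-antitoxin genes (11 of 19). RpoS-dependent genes passed it at 412.6 (50 of 56) and universal stress proteins at 418.5 min (5 of 7). The falls of flagella (52 of 52), ribosomal protein (30 of 54) and nucleotide synthesis genes (22 of 26) passed theirs at 425.4, 430.1 and 431 min. The branched-chain and Lrp-activated lists share leuA, leuB, leuC and leuD, so their midpoints are not separate results.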

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

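Of the tests below, the comparison of crp with the lrp and rpoS strains, the Fisher's exact test of dksA against rpoS, the within-block values of the 6 genes low in lrp and the midpoint times measured from the replete controls with each time point left out were chosen only after the result was seen.

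The starved strains differed from starved wild type, tested gene by gene as the difference itself. The number of genes was 1409 in relA spoT, 1107 in dksA, 1081 in relA, 425 in crp, 83 in rpoS and 21 in lrp. In the relA spoT strain 66 genes lay on the opposite side of the replete wild-type level from starved wild type. Of these 38 were up in wild type and down in the strain. Examples are hdeA, an acid resistance gene (1.36 in wild type, -3.40 in relA spoT), and tpr (-1.59 and 3.81). In relA 41 genes did so, 21 of them up in wild type and down in the strain, such as the leucine gene leuC (3.51 in wild type, -1.87 in relA), the DNA protection gene dps (3.65 and -1.34), sra (4.52 and -1.72) and yhbE (-1.70 and 3.24). These examples were chosen after their values were seen. No mutant was measured replete, so a difference present before starvation cannot be told apart from a response to it.

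Intergenic probe sets, which the comparisons of genes do not use, also carried signal that changed. In starved against replete wild type 28 of 1382 passed (12 higher, 16 lower, on the 8 arrays of the earlier block), and in late against control 195 of 1297 (129 higher, 66 lower).

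Late and early samples of the time course differed in 1660 genes. Of the 35 splits of these 8 arrays into groups of 4, 1 gave as many genes, the real split itself, and the highest of the other splits gave 1 gene. The count thus goes with the order of the samples, and 1 of 35 is the lowest share this test can give. These are serial samples that are not free to trade places, and the real split follows their order, so a drift along the culture is not excluded.

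Ribosomal protein genes were lower in starved crp than in starved wild type, on arrays with a narrow spread of values. The narrow spread as the whole cause is argued against by quantile normalization, after which the median went from -1.09 to -0.687 with 15 of the 24 called members still lower and the list still past its test (adjusted p = 4.83e-08 with the preset correlation; before normalization adjusted p = 0.34 with an estimated correlation). A shift shared by the submission block is argued against by the lrp and rpoS strains, whose lower median was -0.263. Within the block the median in crp was -1.344 (adjusted p = 0.367 with an estimated correlation), on values as deposited. That median is deepened by its reference, which includes dksA. There the list median against starved wild type was 1.307 after quantile normalization. The loss of Crp may lower these genes, by an amount that the within-block value does not give. Growth state at sampling was not tested, and part of the size goes with the array spread.

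RpoS-dependent genes rose in starved wild type and were lower in starved relA, relA spoT and dksA. Narrow arrays as the cause are argued against by quantile normalization, after which at least 98% of the called members stayed lower in each strain (49 of 49 in relA, 50 of 51 in relA spoT and 44 of 44 in dksA). In dksA 7 members were lower than in the rpoS strain of the same block, led by the curli genes csgA (-3.72) and csgD (-2.70), and 6 were higher, with a median of 0.082 over the list. The bound of 6 set beforehand was too low, since 796 of 4222 genes differed between these strains and 5.7 of the 56 would be lower at the rate of all genes (one-sided Fisher's exact p = 0.35), so the loss of RpoS as the whole cause cannot be told apart from a further effect of DksA. RpoS protein was not measured, and a role of the lower rpoS transcript in relA and relA spoT stays open, as untested.

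Genes low in lrp passed the midpoint of their rise before genes low in rpoS. That small rises cross early by chance cannot be told apart from a real difference, since only 4 rpoS genes had rises of the same size (later by 32 min). That a single time point sets the difference cannot be told apart either, since without the 340 min array 1 lrp gene was left (8.1 min). The 340 min array as the source of the starting level is not settled by the replete controls. Measured from them, the difference was at least 36.7 min without each time point in turn. That lowest value came without 340 min, where genes already past their midpoint at 370 min were given that time. The controls also had 400 uM isoleucine, and branched-chain genes already stood 0.461 above them at 340 min. Genes low in lrp may rise earlier, over 6 genes that include 3 of the leu operon. Of these 6 genes 4 (leuD, leuC, dadX and aceA) did not pass in lrp within the block (-0.87, -0.50, -0.39 and 0.09). There the other strains include dksA (leuC -3.30, aceA -3.08).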

How the results depend on the processing

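The fits without the 5 arrays of narrow spread, without the probe sets named for another strain, quantile normalization for the counts by strain, and the within-block values of gene lists in crp and dksA were chosen only after the data were seen.

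Over all alternatives 457 counts stayed within 1.5 times their value and 108 did not. List tests kept their direction and their side of the threshold in 1173 cases, lost their call in 247, gained one in 20 and turned without a call in 46. For named genes these numbers were 12762, 706, 83 and 41. Many of these fits could not change a difference and altered only its spread. Among them are fits without an array of neither group compared, with a variance trend or with array weights. The estimated correlation likewise cannot change the direction of a list test. The tallies of unchanged results are thus partly fixed in advance. Called lists whose test changed direction were 9 and called genes 5, all given below. In 5 more lists that lost their call the median alone changed sign: DNA replication in dksA against replete wild type (0.106) and early ribosomal proteins (0.006) after quantile normalization, and the TCA cycle (0.137), fatty acid synthesis (0.03) and aminoacyl-tRNA synthetases (0.007) in dksA within the block. With the replicate block (the replicate number as a term) each count stayed within 1.5 times its value, for example 899 in starved against replete wild type, 1082 in relA, 84 in rpoS and 19 in lrp against starved wild type. The numbers pair no arrays: residuals of 28 group pairs correlated at -0.412 to 0.652 across genes, 10 above 0.1 and 9 below -0.1. Signal over background limits genes near the intergenic level.

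Leaving out 1 array, which leaves its group with 1 array assumed to vary like the others, gave these ranges. Against starved wild type the counts were 669 to 1781 in relA, 411 to 1671 in dksA, 50 to 119 in rpoS, 4 to 42 in lrp and 32 to 995 in crp. Against replete wild type they were 547 to 1272 in wild type, 375 to 1650 in relA, 556 to 1367 in relA spoT, 523 to 1814 in dksA, 411 to 1165 in rpoS, 698 to 1422 in lrp and 834 to 1934 in crp. In the time course they were 3 to 179 early and 1300 to 2092 late, and the difference in midpoint time was 8.1 to 37.7 min, lowest and no longer significant without the 340 min array.

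Lists past the list test fell with quantile normalization from 16 to 4 in dksA against replete wild type and from 15 to 7 in both dksA and crp against starved wild type. In dksA the median of aminoacyl-tRNA synthetases turned to 0.291 and in crp that of RpoS-dependent genes to 0.03. The cause was not tested. The estimated correlation was far above the preset 0.01 (0.299 for branched-chain synthesis and 0.536 for ribosomal proteins in wild type), and with it 2 lists passed in wild type. Against replete wild type 1 list passed in each of relA, relA spoT, dksA and rpoS and 2 in each of lrp and crp. In the comparison with starved wild type 1 passed in each of relA, relA spoT, dksA and lrp and 0 in crp, and in the time course 0 passed late, 0 early and 0 late against early. For crp, with limma's preset correlation, 15 had passed, and 1179 genes had an unadjusted p under 0.05.

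Counts moved as follows. With all probe sets 243 passed in rpoS, 182 in lrp and 852 in crp against starved wild type. There 466 intergenic probe sets of the later block appear to hold another probe set's values (r = 0.096 with starved wild type, against 0.944 for the authors' differences). With only the compared groups in the fit 202 passed in relA and 2237 in dksA against replete wild type, and 235 in relA against starved wild type. Array weights gave relA arrays 0.199 each and replete wild type up to 2.538. With them 1437 passed in wild type, and against replete wild type 264 in relA, 1627 in relA spoT, 2226 in dksA, 1316 in rpoS, 1711 in lrp and 2190 in crp. In the comparison with starved wild type they gave 410 in relA, 55 in lrp and 855 in crp. Without the 5 narrow arrays 36 passed in lrp. The discordant relA pair enters the spread that the 8 groups share, so it lowers counts in comparisons without relA as well. Beyond that, the cause of these shifts was not tested.

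Within the later block 277 genes passed in lrp and 269 in rpoS, and 7 and 16 lists with the preset correlation. With an estimated correlation 1 list was left in each, RpoS-dependent genes (adjusted p = 0.00391 and 0.00713). By construction the other 3 strains of lrp and crp include dksA and rpoS, and those of rpoS include dksA. RpoS-dependent genes are low in both dksA and rpoS, while branched-chain and Lrp-activated genes are low in dksA and not in rpoS. For dksA they include the crp strain, in which the crp transcript is low (-5.95 within the block), as are ribosomal protein genes (median -1.086 against starved wild type). The list test turned in crp for RpoS-dependent (median 1.177) and Lrp-activated genes (0.761). In lrp it turned for other amino acid synthesis (0.071), RpoS-dependent genes (1.212), flagella (-0.067) and fatty acid synthesis (0.1), and for branched-chain synthesis, whose median stayed negative (-0.203). Genes that turned were leuD (0.076), ycgB (0.164) and ybaY (0.632) in crp, crp in dksA (0.365) and aceA in lrp (0.092).

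In the time course, centring each array gave 68 early genes, and 3-point windows gave 15. A minimum change of 1 log2, which removes genes by construction, gave 971 late, 23 early, 632 late against early and 852 for the spline. In the counts of responding genes by strain this minimum gave 286 rising and 194 falling genes in relA, 302 and 244 in relA spoT, 98 falling in dksA and 75 rising in crp. With the response taken from the strain arrays, where fewer genes respond, falling genes numbered 173 in relA (40.6% of those that fell), 207 in relA spoT (48.6%), 101 in dksA (23.7%), 1 in lrp and 15 in crp (3.5%), and rising genes 7 in lrp (1.5%). Quantile normalization gave 232 falling genes in dksA and 50 in crp, and leaving out the narrow arrays 21 rising genes in lrp.

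The other table of the same arrays holds equal values in the 8 columns that both name, so that alternative was not run. A minimum rise of 2 log2 left no lrp gene for the midpoint times.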

Other observations

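Of the tests in this part, the within-block list test in dksA was chosen only after the data were seen. The gene groups and genes described were picked after their values were seen.

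The relA spoT strain had higher SOS genes than starved wild type, 12 of 19 (13 adjusted over the list alone, median 1.13, adjusted p = 3.82e-06, and 0.189 with an estimated correlation). Among them were yebG (2.99 ± 0.36), dinF (2.12 ± 0.25), dinG (2.11 ± 0.33), recN (2.10 ± 0.34), recA (1.67 ± 0.33), which encodes the recombinase that sets off the SOS response, and lexA (1.55 ± 0.46), its repressor. In relA 1 SOS gene was higher and the list did not pass (median 0.38, adjusted p = 0.095), though it passed after quantile normalization (adjusted p = 0.0299). Toxin-antitoxin genes were higher in 8 of 18 cases in relA spoT (median 0.98, adjusted p = 0.00064, and 0.215 with an estimated correlation), led by higA (4.37) and higB (4.35). Iron acquisition genes were higher than in starved wild type in 14 of 35 cases in relA (19 adjusted over the list alone, median 0.94, adjusted p = 0.000539, and 0.464 with an estimated correlation). They include fhuF (2.88 ± 0.32), the enterobactin gene entC (2.73) and exbB (2.55). Another 4 were lower, the iron-sulfur cluster genes sufD (-1.78), sufB (-1.65), sufC (-1.51) and sufS (-1.07). NADH dehydrogenase genes such as nuoK (-3.67), nuoM (-3.40) and nuoJ (-3.22) were lower in relA, where 11 of 21 genes of the ATP synthase and NADH dehydrogenase list were lower and 1 higher (12 and 1 adjusted over the list alone, median -1.50, adjusted p = 2.6e-06, and 0.311 with an estimated correlation).

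In dksA 4 nitrogen-limitation genes were higher than in starved wild type, glnK (2.82 ± 0.30), glnA (2.33), nac (1.58) and amtB (1.23), though the list did not pass (median -0.04 while the test points up, adjusted p = 0.411). Within the later block 5 were higher and 1 lower (adjusted p = 0.0726), with glnK at 2.39. In crp the cell division genes minE (-2.73), minD (-2.35) and ftsZ (-1.86) and the nucleoid gene hns (-1.97) were lower than in starved wild type, and lower within the block (-2.04, -1.76, -1.64 and -1.41). Of the 25 genes of the DNA replication and cell division list 4 were lower and 1, dnaG, higher, and the list did not pass (median -0.50, adjusted p = 0.0709, and 0.808 after quantile normalization). The regulator gene fis, which fell in starved wild type, was higher than there in relA (2.58), relA spoT (3.49) and dksA (2.29, and 2.40 within the block).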
